A study of Homo sapiens with 18 samples.

How the data were processed

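The series measured RNA in U87, an established human glioblastoma line, after 1 treatment of 24 h with 100 nM of a rexinoid or with ethanol. Per the labels' protocols, total RNA was depleted of ribosomal RNA by probes, sheared, primed at random and sequenced as paired reads. The 18 libraries fell into 6 groups of 3, taken from the treatment named in each library's labels: ethanol, bexarotene, A34, A41, A80 and A98. The deposited tables of the A98 group carry the code A90 in their names, and the replicate numbers there differ in part from those of the titles. Groups and replicate numbers here follow the labels. No label says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

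Per the submitters' processing notes, STAR, StringTie and MultiQC were used with build GRCh38; their versions, the gene annotation release and the handling of strand are not given in the sources used here. Each library had 1 table of StringTie gene abundances with 3 measurement columns. TPM is a share of all transcripts in a library that the authors computed, per the file headers. FPKM, fragments per kilobase scaled to mapped fragments, stood beside it in the same deposited tables. Coverage, the mean signal in reads per base of a gene, was the deposited column that still holds depth. The tables listed 60675 gene IDs, of which 58444 were in the reference annotation used here (GENCODE release 29, which may differ from the authors' annotation). Between 2 and 3 entries of a library repeated a gene ID, and their values were summed. Coordinates are those of the deposited tables, on GRCh38.

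The tables hold no read counts, so no count model was used. Depth was taken from the ratio of coverage to FPKM, which is constant within a library and gives the aligned bases behind it. It ranged from 1.31 to 3.89 gigabases with a median of 2.08, which limits the precision of genes near 1 TPM most. TPM is a share of each library, so a library in which ribosomal RNA takes a large part of TPM has lower values for every other gene. TPM was therefore divided by a median-of-ratios factor (0.417 to 1.20) made from 16349 genes above 0 in every library, and the result is called scaled TPM. The ribosomal RNA share was the summed TPM of nuclear and mitochondrial ribosomal RNA genes.

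Genes with at least 1 TPM in at least 3 of the 18 libraries were tested, 18269 in all. Log2(scaled TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 for all 18 libraries and 6 groups in 1 model with 12 residual degrees of freedom, moderated with a trend on mean level (prior degrees of freedom 3.39). Every adjusted p for a gene in the text is from limma, two-sided, with Benjamini-Hochberg adjustment over all genes tested in that comparison, and 0.05 was the threshold. Fold changes are on the log2(scaled TPM + 1) scale, which understates the change of low genes, and intervals are 95%. The comparisons were each rexinoid against ethanol, each coded rexinoid against bexarotene, the coded rexinoids against each other, the mean of the 5 rexinoids against ethanol, and an F test for any difference among the 5. Replicates were compared first: no 2 libraries held identical values, with 0 such pairs, and Pearson's r across genes lay between 0.951 and 0.981 within groups, against at most 0.982 between libraries of different groups.

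The groups, tests, 29 gene lists and the rule for named genes were fixed before the data were examined. For each rexinoid against ethanol the rule took, among genes past the threshold whose 3 libraries of a group all lay above the other 3 and whose higher group mean was at least 2 scaled TPM, the 10 with the largest increase and the 10 with the largest decrease (5 and 5 against bexarotene). It added 22 receptor and target genes named in every comparison, and the 4 members of smallest p from each list past its threshold. Genes spanning fewer than 300 bases were left out of the rule. Lists were tested with camera in limma with a preset correlation of 0.01, again with an estimated correlation, and with fry. The list adjusted p values are from camera with the preset correlation unless another is named, adjusted over the 26 lists tested in a comparison. A list was tested if at least 3 members passed the filter. The oligodendrocyte, endothelial and microglia and leukocyte lists had 2 such members each and are given as levels. The fatty acid synthesis and LXR lists share 3 members (SCD, SREBF1 and FASN), and the RAR and receptor lists share RARA and RARB.

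Agreement between rexinoids was set against 100 simulations in which all 18 libraries were unchanged and the rexinoid groups shared 1 set of simulated ethanol libraries. Noise was drawn independently for each gene and with the same spread in every library, so structure between libraries is not in the simulations. The fitting steps were tested on simulated data. In the simulation of A41 against ethanol over 17741 genes, 44.78% of genes changed by 0.5 on the log2 scale were recovered, 76.12% at 1 and 92.42% at 2, and 6 of 148 calls were false. The changed genes were drawn only from those with a mean above about 2 scaled TPM, so recovery of lower genes was not measured. Here too the noise was independent between genes and equal between libraries. Alternatives covered the pseudocount, the filter, the scaling, the FPKM column, the moderation, library weights, a replicate block, each library left out, and each pair of groups fitted alone. Leaving out the 3 libraries rich in ribosomal RNA and using the ribosomal RNA share as a covariate were chosen after seeing the data. Tables were read and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.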

Results

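RNA was measured in U87, an established line of human glioblastoma cells, 24 h after a single dose of 100 nM rexinoid or of ethanol, the vehicle. Rexinoids are ligands of the retinoid X receptors (RXR), nuclear receptors that bind DNA as partners of the retinoic acid receptors (RAR), the liver X receptors (LXR) and other receptors. The 18 libraries formed 6 groups of 3: ethanol, bexarotene (an RXR agonist in clinical use) and 4 rexinoids given by the codes A34, A41, A80 and A98. Ethanol and bexarotene served as controls, so the comparisons ask which genes each rexinoid changed and where the coded compounds differed from bexarotene and from each other. Each library rested on 1.31 to 3.89 gigabases of aligned sequence, and 13116 to 16630 genes reached 1 TPM. Ribosomal RNA made up 35.5% of TPM in ethanol replicate 2, 44.9% in bexarotene replicate 1 and 56.1% in A41 replicate 2, against 0.366% to 4.43% in the other 15 libraries. Levels are therefore given as TPM scaled by median of ratios, as mean ± SD with n = 3 libraries per group.

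**Figure D1:**
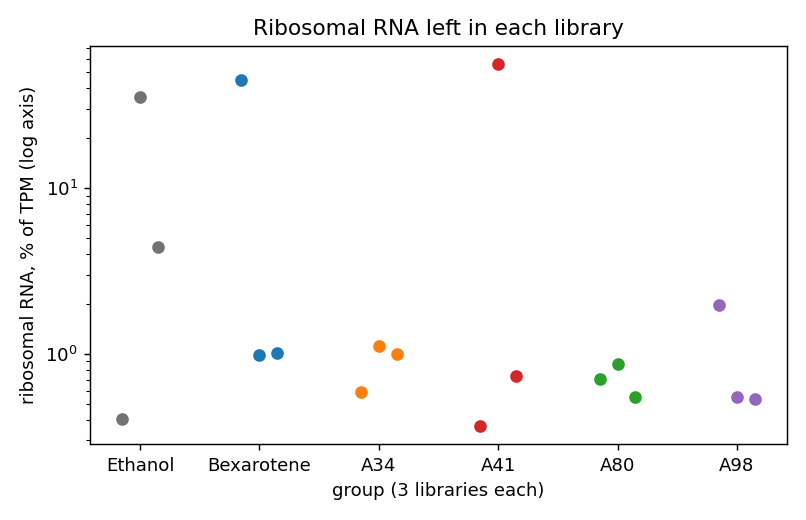
Share of TPM assigned to ribosomal RNA genes (percent, log axis) in each of the 18 libraries, by group. Ethanol replicate 2, bexarotene replicate 1 and A41 replicate 2 lie between 35.5% and 56.1%, and the other 15 between 0.366% and 4.43%.

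The cells expressed mesenchymal genes at high level and several receptors through which a rexinoid can act. Over the 18 libraries, vimentin (VIM) averaged 4058 scaled TPM, the hyaluronan receptor CD44 averaged 1015 and fibronectin (FN1) averaged 299, and of astrocyte genes CLU averaged 199, GJA1 69.2, SLC1A3 20.9 and the filament gene GFAP 0.788. Among RXR genes, RXRB averaged 9.05 and RXRA 5.68, and RXRG averaged 0.120 and stayed below the level for testing. Of the partners, the LXR gene NR1H2 averaged 41.1, RARG 27.98, the vitamin D receptor gene VDR 23.5, RARA 18.05, RARB 6.53, NR1H3 6.31 and PPARG 3.20. Markers of other cell types varied in level. The neuronal genes ENO2, TUBB3, SNAP25 and GAP43 averaged 161, 69.0, 14.2 and 10.2. Low values were found for the leukocyte gene PTPRC at 0.0574, the epithelial EPCAM at 0.939, the oligodendrocyte MBP at 1.24 and the endothelial KDR and TEK at 1.88 and 1.65. The oligodendrocyte gene CNP averaged 29.2, and the myeloid genes CD68 and CSF1R averaged 177 and 12.4.

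Bexarotene raised 10 genes against ethanol and lowered 0 by limma (1051 genes had an unadjusted p under 0.05). CYP26B1, which encodes an enzyme that degrades retinoic acid, rose from 3.97 ± 0.93 to 14.2 ± 1.6, a log2 fold change of 1.62 (SE 0.20, adjusted p = 0.0024). DHRS3, a retinaldehyde reductase, rose from 35.0 ± 4.3 to 67.0 ± 4.1 (log2 fold change 0.92, SE 0.09, adjusted p = 0.00029). Of lipid genes, the cholesterol exporter ABCA1 rose from 23.0 ± 1.2 to 50.2 ± 4.4 (log2 fold change 1.09, SE 0.12, adjusted p = 0.0013) and the stearoyl-CoA desaturase SCD from 45.8 ± 5.1 to 121 ± 3.9 (1.39, SE 0.16, adjusted p = 0.0013). OLMALINC, a long noncoding RNA, rose by 1.25 (adjusted p = 0.0094), the secretory pathway kinase FAM20C by 0.94 (0.0093), LINC00339 by 0.75 (0.018), the acyl-CoA synthetase ACSL3 by 0.47 (0.018) and the differentiation inhibitor ID1 by 0.38 (0.041). The remaining call, the small nuclear RNA gene RNU6-8 at 1.62 (adjusted p = 0.018), was named after its value was seen. On GRCh38, CYP26B1 (ENSG00000003137) spans bases 72129238 to 72148038 of chromosome 2, DHRS3 bases 12567910 to 12618210 of chromosome 1, ABCA1 bases 104781006 to 104928155 of chromosome 9, SCD (ENSG00000099194) bases 100347233 to 100364826 of chromosome 10 and OLMALINC bases 100373099 to 100454043 of the same chromosome. The lipogenic regulator SREBF1 (log2 fold change 0.81, adjusted p = 0.84), the lipase inhibitor ANGPTL4 (1.44, 0.84), TGM2 (0.29, 0.84) and RARB (0.22) did not pass. CYP26B1, SCD, ABCA1 and DHRS3 stayed past the threshold whichever 1 of the 6 libraries was left out, while FAM20C was lost without ethanol 1 (adjusted p = 0.060), OLMALINC without ethanol 1 (0.060), bexarotene 2 (0.057) or bexarotene 3 (0.055), ACSL3 without any 1 ethanol library or bexarotene 2, and LINC00339 and ID1 without any 1 of the 6. The count was 5 without ethanol 1, 6 without ethanol 2, 6 without ethanol 3 and 5 without bexarotene 2. Without the 3 libraries rich in ribosomal RNA it was 2, DHRS3 (adjusted p = 0.0041) and ABCA1 (0.023), while CYP26B1 had 0.18, SCD 0.073 and FAM20C 0.18.

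A34 raised 13 genes and lowered 2 against ethanol. The lipid genes moved by 1.91 for SCD (178 ± 41, adjusted p = 1.7e-05) and 1.49 for ABCA1 (66.9 ± 12, 1.7e-05), and the retinoid genes by 1.94 for CYP26B1 (18.4 ± 5.9, 0.00018) and 1.14 for DHRS3 (78.0 ± 3.9, 1.5e-05). FAM20C rose by 1.36 (adjusted p = 0.00011), OLMALINC by 1.57 (0.00055), ACSL3 by 0.60 (0.00095), LINC00339 by 0.79 (0.0097), the mucin-type glycosyltransferase GALNT12 by 0.83 (0.022) and the synaptic protein gene RIMS3 by 0.91 (0.046). The metalloprotease ADAMTS1 fell from 46.2 ± 4.5 to 29.98 ± 2.2 (log2 fold change -0.61, SE 0.10, adjusted p = 0.046) and the chromatin protein HMGA2 from 132 ± 6.9 to 97.6 ± 2.9 (-0.44, SE 0.08, adjusted p = 0.046). SREBF1 had a log2 fold change of 1.13 with adjusted p = 0.065, and ANGPTL4 2.58 with 0.18. ADAMTS1 and HMGA2 were each lost when any 1 of the 6 libraries was left out. GALNT12 was lost without ethanol 1 or 3 or A34 1 or 2, RIMS3 in 5 of the 6 omissions and LINC00339 without ethanol 2 or 3. The count was 9 without ethanol 1, 9 without ethanol 2 and 8 without ethanol 3. A replicate block from the titles gave 166 genes for A34, 197 for A41 and 13 for bexarotene against ethanol. The block from file numbers gave 57, 116 and 8. ANGPTL4 passed with A34 under either block. The number of genes called for A34 thus depends on whether the replicate number is modelled.

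A80 raised 8 genes and A98 raised 6 against ethanol, with 0 lowered by either in limma (1720 and 1211 genes had an unadjusted p under 0.05). CYP26B1 rose to 13.3 ± 2.7 with A80 (log2 fold change 1.53, SE 0.20, adjusted p = 0.0056) and to 14.5 ± 1.4 with A98 (1.66, SE 0.20, 0.0014). DHRS3 rose by 0.97 with A80 (adjusted p = 0.00013) and 0.95 with A98 (0.00016), SCD by 1.21 (0.0056) and 1.58 (0.00023), ABCA1 by 0.83 (0.013) and 1.28 (0.00016), and FAM20C by 1.17 (0.0015) and 1.10 (0.0014). ECH1, an enzyme of fatty acid oxidation, rose by 0.52 with A80 (adjusted p = 0.019) and 0.53 with A98 (0.021). LINC00339 (0.84, adjusted p = 0.0084) and ID1 (0.42, 0.019) also rose with A80. In the A80 comparison only FAM20C and DHRS3 stayed past the threshold under every single omission. CYP26B1 was lost without ethanol 2 (adjusted p = 0.053) or A80 1 (0.051), and SCD without ethanol 3 (0.057) or A80 1 (0.051). ABCA1 was lost in 5 of the 6 omissions (0.056 to 0.12). The A80 count was 5, 3 and 3 without ethanol 1, 2 and 3, 2 without A80 1, 5 without A80 2, and 2 without the 3 libraries rich in ribosomal RNA. With a replicate block from the titles the A80 count was 117 and the A98 count 8. With the block from file numbers they were 51 and 15, so the A80 count too depends on modelling the replicate number. For A98, ECH1 was lost in 5 of the 6 omissions and the other 5 genes in none.

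**Figure D2:**
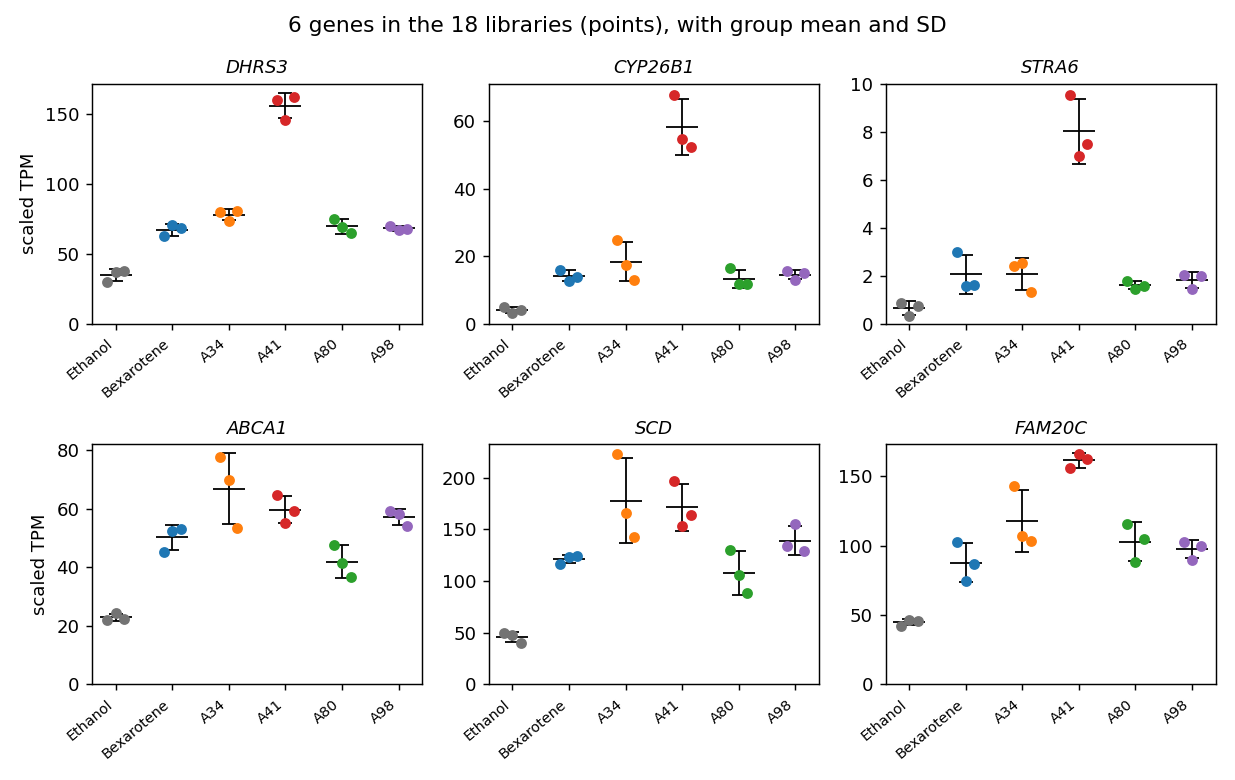
Scaled TPM of DHRS3, CYP26B1, STRA6, ABCA1, SCD and FAM20C in each library (points) with group mean and SD, for ethanol and the 5 rexinoids. CYP26B1 averaged 58.3 with A41 and between 13.3 and 18.4 with the other rexinoids, while ABCA1 averaged 59.7 with A41 and 66.9 with A34.

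A41 changed 138 genes against ethanol, 93 higher and 45 lower. Of RAR target genes, CYP26B1 rose from 3.97 ± 0.93 to 58.3 ± 8.4 (log2 fold change 3.59, SE 0.20, adjusted p = 7.4e-08), DHRS3 to 156 ± 9.0 (2.13, SE 0.09, 1.5e-09) and STRA6, the cell-surface receptor for retinol-binding protein, from 0.645 ± 0.29 to 8.02 ± 1.3 (2.46, SE 0.21, 1.1e-05). PTGES, a prostaglandin E synthase, rose from 28.8 ± 4.5 to 129 ± 24 (log2 fold change 2.12, adjusted p = 2.4e-06), the transglutaminase TGM2 from 165 ± 4.3 to 346 ± 21 (1.06, 4e-06), the anticoagulant receptor THBD from 2.33 ± 0.15 to 8.46 ± 2.2 (1.48, 0.00092) and the cytokine LIF from 70.9 ± 8.6 to 183 ± 42 (1.33, 0.023). FAM20C rose by 1.83 (adjusted p = 1.7e-06), the serpin SERPIND1 by 1.69 (0.0016) and GALNT12 by 1.65 (5.4e-06). The lipid genes rose by 1.88 for SCD (adjusted p = 8.2e-06), 1.34 for ABCA1 (1.8e-05) and 1.06 for SREBF1 (0.024). STX16-NPEPL1, annotated as a readthrough of STX16 and NPEPL1 (chromosome 20, bases 58651434 to 58715410), was at 282 ± 140 against 0.836 ± 0.85 (log2 fold change 7.24, SE 1.30, adjusted p = 0.013), and BGLAP at 6.83 ± 1.4 against 0.00374 (2.95, 0.0058). Both overlap other genes and the handling of strand is not given in the sources used here, so their levels are uncertain. STRA6 spans bases 74179466 to 74212267 of chromosome 15, PTGES bases 129738331 to 129753042 of chromosome 9 and TGM2 bases 38127385 to 38166578 of chromosome 20.

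Among the genes that A41 lowered, HGF, the ligand of the MET receptor, fell from 7.97 ± 0.38 to 3.89 ± 0.33 (log2 fold change -0.88, SE 0.10, adjusted p = 0.00036), and HMGA2 fell from 132 ± 6.9 to 75.0 ± 5.5 (-0.81, SE 0.08, 2.7e-05). The epidermal growth factor receptor ligand EREG fell by 1.06 on the log2 scale (adjusted p = 0.0089), ADAMTS1 by 0.97 (0.00013), the sphingolipid enzyme SPTLC3 by 0.86 (0.0066), EVI2A by 0.81 (0.0058), the growth factor signalling antagonist SPRY2 by 0.79 (0.00084), the chemokine CCL3 by 1.17 (0.028) and the matrix protein THBS1 by 0.89 (0.042). The cystine transporter SLC7A11 fell by 0.68 (adjusted p = 0.048), the glutathione synthesis gene GCLM by 0.63 (0.046) and CD44 by 0.38 (0.027). Of the 30 named genes that passed, 19 stayed past the threshold under every single omission. SREBF1 and FADS1 were lost whichever library was left out, STX16-NPEPL1 without ethanol 1 or 2 or A41 2 or 3, EREG without A41 2 or 3, VDR in 4 omissions, and CCL3, THBS1, SLC7A11, GCLM, LIF and CD44 in 5. The A41 count was 73, 76 and 71 without ethanol 1, 2 and 3, 79 without A41 2 and 79 without A41 3, and 48 without the 3 libraries rich in ribosomal RNA, where STX16-NPEPL1 had an adjusted p of 0.22, SREBF1 0.19 and BGLAP 0.070.

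The lists of RAR and LXR target genes rose with every rexinoid by camera, which compares a list with all other genes. TPM as deposited moved the median of all genes by -0.27 to 0.15 against ethanol, and relative to that median 3 of 121 called list changes turned sign under another scaling. They were the ribosomal protein genes with bexarotene and with A41 against ethanol, and the mitochondrially encoded genes for A41 against A98. Of 13 tested RAR target genes, 6 rose with A41 (CYP26B1, DHRS3, STRA6, TGM2, the corepressor NRIP1 and the homeobox gene HOXA5) and 10 when adjusted over the list alone, with a median log2 fold change of 0.76 (camera adjusted p = 3.9e-22). HOXA5 did not pass with A41 without the 3 libraries rich in ribosomal RNA (limma adjusted p = 0.14). With each other rexinoid CYP26B1 and DHRS3, 2 of the 13, passed, and 5 with bexarotene and 4 with A34, A80 and A98 when adjusted over the list alone (camera adjusted p = 6.5e-06, 1.5e-07, 1.7e-06 and 4.7e-07). The RAR list had adjusted p = 0.052 with an estimated correlation for bexarotene and adjusted p = 0.084 with an estimated correlation for A80, and held for A34 (0.027), A41 (0.00033) and A98 (0.020). Its library means differed by replicate number (exact permutation p = 0.00836, 0.0104 adjusted over 5 lists), while for the LXR list that p was 0.109. Of 11 LXR target genes, ABCA1 and SCD passed as higher with every rexinoid and SREBF1 with A41, and 4 passed in each comparison when adjusted over the list alone. The LXR list had camera adjusted p = 2.6e-07 with bexarotene, 4.6e-06 with A34, 4.5e-07 with A41, 0.00082 with A80 and 3.5e-08 with A98. It was lost for A80 (adjusted p = 0.15 with an estimated correlation). Of 12 fatty acid synthesis genes, SCD, SREBF1 and the desaturase FADS1 rose with A41 (6 when adjusted over the list alone, camera adjusted p = 4.5e-07), and SCD with the others (3 when adjusted over the list alone with bexarotene, A34 and A98). That list passed with bexarotene (0.014) and A34 (0.0086), where it had adjusted p = 0.10 and 0.070 with an estimated correlation, held in both tests with A98 (0.00022), and did not pass with A80 (0.25).

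The cholesterol synthesis list of 23 genes passed with bexarotene, A34, A41 and A98 (camera adjusted p = 0.0048, 0.016, 5.7e-06 and 3.4e-05), with the regulator SREBF2 higher in A41 by 0.49 (adjusted p = 0.0056) and 7 genes higher there when adjusted over the list alone. These calls had adjusted p = 0.35, 0.30, 0.083 and 0.14 with an estimated correlation. Of 6 vitamin D and thyroid receptor targets, THBD rose with A41, and the list passed with bexarotene (0.030), A34 (0.0023), A41 (0.0074) and A80 (0.022), each lost with adjusted p = 0.32, 0.092, 0.13 and 0.19 with an estimated correlation. Of 21 receptors and cofactors, VDR rose by 0.49 with A41 (adjusted p = 0.018), and the list had camera adjusted p = 0.033 there and adjusted p = 0.21 with an estimated correlation. The PPAR list of 14 genes, with ANGPTL4, PLIN2, PDK4 and CPT1A among them, passed with none of the 5 (camera adjusted p from 0.066 with A98 to 0.60 with A80). With A41, the list of 10 NRF2 antioxidant genes was lower (0.0052, or adjusted p = 0.13 with an estimated correlation), and GCLM and SLC7A11 passed alone. That of 20 mesenchymal genes was also lower (0.0012, or adjusted p = 0.39 with an estimated correlation), and THBS1 and CD44 passed alone. The mesenchymal list was also lower with bexarotene (0.0048, or adjusted p = 0.50 with an estimated correlation), where no member passed alone.

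Stress-related lists lay higher with the rexinoids, but none of these calls held with an estimated correlation. All 17 hypoxia and glycolysis genes had positive changes with A34, and 16 passed with A34 and 16 with A80 when adjusted over the list alone (camera adjusted p = 2.1e-12 and 4.5e-14), while 0 passed over all genes in limma. Examples are the stress gene NDRG1 at 1.95 with A34 and 2.01 with A80 (adjusted p = 0.23 and 0.26) and the angiogenic factor VEGFA at 0.77 and 0.78 (0.22 and 0.26). These values are from the model without a replicate block. Under either block NDRG1 and VEGFA, and DDIT4 named below, passed with A34 and with A80. The hypoxia list also passed with bexarotene (9.6e-05), A41 (0.014) and A98 (5.4e-08), and the 5 calls had adjusted p = 0.50, 0.19, 0.64, 0.19 and 0.33 with an estimated correlation for bexarotene, A34, A41, A80 and A98. Per-library means of the list, relative to ethanol, ran from 0.40 to 1.49 within A34 and from 0.44 to 1.48 within A80. They differed by replicate number over the 6 groups (exact permutation p = 0.000257, 0.000643 adjusted over 5 lists). This test was chosen after the values were seen. Of 18 genes of the unfolded protein and amino acid stress response, 11 passed with A34 and 11 with A80 when adjusted over the list alone, among them DDIT4 at 1.36 and 1.55 (adjusted p over all genes 0.16 and 0.17). That list had camera adjusted p = 0.0019, 2.2e-08, 4.9e-10 and 2.7e-05 with bexarotene, A34, A80 and A98, lost with adjusted p = 0.50, 0.17, 0.19 and 0.30 with an estimated correlation, and 0.25 with A41. The NF-kB list of 19 genes passed with all 5 (7.6e-06 with bexarotene, 2.5e-07 with A34, 0.00055 with A41, 1.7e-06 with A80 and 2.6e-05 with A98) and had adjusted p = 0.32, 0.17, 0.38, 0.19 and 0.29 with an estimated correlation. LIF rose with A41, and 7 members passed with A34 when adjusted over the list alone. The means of the unfolded protein list and of the NF-kB list also differed by replicate number (exact permutation p = 0.000129 and 0.000772, or 0.000643 and 0.00129 adjusted over the 5 lists).

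The S phase list of 23 genes was lower with A34 (camera adjusted p = 0.00036) and A80 (0.0083), with adjusted p = 0.30 and 0.53 with an estimated correlation, and the G2/M list of 24 genes was higher with A41 (0.0052, or adjusted p = 0.39 with an estimated correlation). No member of either list passed alone. The 13 mitochondrially encoded protein genes were lower with A80 (0.00026, or adjusted p = 0.54 with an estimated correlation), and A80 replicate 3 stood at -1.37 against the ethanol mean. Ribosomal protein genes passed with bexarotene (0.042), A41 (0.035), A80 (0.0011) and A98 (0.0025), with adjusted p = 0.50, 0.39, 0.19 and 0.29 with an estimated correlation. Their median turned negative under quantile normalization with bexarotene (-0.07) and A41 (-0.04). The list of 14 structured small RNAs and ribosomal RNAs passed with bexarotene (0.0042) and A41 (0.0030), and had adjusted p = 0.50 and 0.44 with an estimated correlation. Both groups held a library rich in ribosomal RNA, as did ethanol. The called lists were rerun without these libraries. The outcome for this list is not given here, so their part in it stays open. The remaining lists passed against ethanol with none of the 5 rexinoids. Their lowest camera adjusted p values were 0.23 for interferon-stimulated genes, 0.39 for p53 targets, 0.058 for astrocyte, 0.088 for glioma stem cell, 0.14 for neuronal and 0.29 for epithelial markers, 0.25 for immediate early and heat shock genes, 0.31 for the nuclear-encoded respiratory chain and 0.063 for replication-dependent histones.

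**Figure D3:**
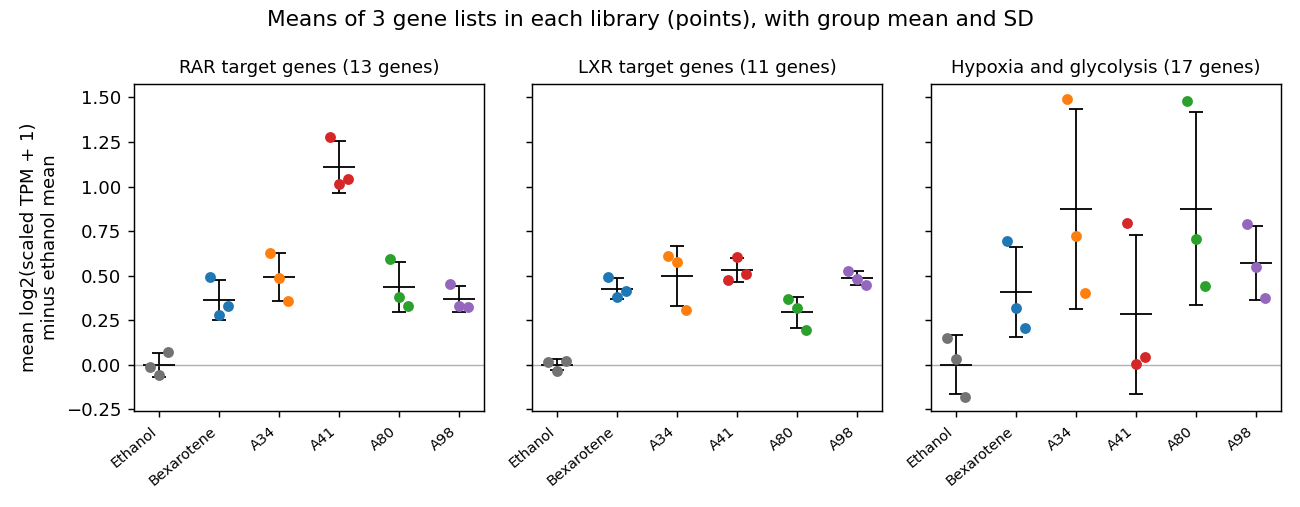
Mean log2(scaled TPM + 1) of 13 RAR target genes, 11 LXR target genes and 17 hypoxia and glycolysis genes in each library, minus the mean of the ethanol libraries. A41 libraries lie between 1.01 and 1.28 in the RAR list and the other rexinoid libraries between 0.277 and 0.627.

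The genes that passed the threshold with every rexinoid were 5, all higher: CYP26B1, SCD, ABCA1, FAM20C and DHRS3. Without the 3 libraries rich in ribosomal RNA, only DHRS3 passed with every rexinoid. There CYP26B1, SCD and FAM20C were lost with bexarotene (adjusted p = 0.18, 0.073 and 0.18). With A80, CYP26B1, SCD and ABCA1 were lost there (0.072 each). Other genes rose with every rexinoid without passing in each, as ECH1 by 0.43 with bexarotene (adjusted p = 0.095). ECH1 and ID1 passed with 4 rexinoids, ACSL3, LINC00339 and OLMALINC with 3. A further 5 genes passed with 2 rexinoids and 125 with 1. In the mean of the 5 rexinoids against ethanol, 33 genes were higher and 4 lower, among them CYP26B1 (log2 fold change 2.07, 95% interval 1.74 to 2.39, adjusted p = 5.3e-06), DHRS3 (1.22, 1.3e-07), STRA6 (1.14, 0.0043), SREBF1 (0.92, 0.025) and, lower, HGF (-0.56, 0.0043), ADAMTS1 (-0.61, 0.002) and HMGA2 (-0.46, 0.0016). The mean count was 20, 15 and 17 without ethanol 1, 2 and 3, and 16 without the 3 libraries rich in ribosomal RNA. Of the 138 genes that A41 changed, 131 had the same sign with all 4 other rexinoids and 14 passed with at least 1 of them, and 14 of the 16 genes called with the others passed with A41. All these changes subtract the same 3 ethanol libraries, which alone favours equal signs, and the share of equal signs over all genes was not counted. Bexarotene and A34 shared 9 higher genes where independent lists give 0.00712, and A34 and A41 shared 12 higher and 2 lower genes against 0.0662 and 0.00493. Simulated unchanged groups shared at most 0.01. Across genes, which are not independent replicates, Pearson's r of fold changes ran from 0.418 for bexarotene and A98 to 0.678 for A34 and A80. In simulated unchanged groups that shared simulated ethanol libraries it was 0.498 to 0.504. The simulated noise was independent between genes and equal between libraries, unlike the spread by replicate number seen in the data. The covariance exceeded the simulated value by 0.0275 for A34 and A80, by 2.7e-05 for bexarotene and A80, and lay at -0.0049 from it for bexarotene and A98. With 3 ethanol libraries the controls could not be split with 2 in each part, so some of any excess may come from the shared controls.

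A41 differed from bexarotene in 21 genes, 19 higher and 2 lower. Of the tested RAR target genes, 6 of 13 were higher (camera adjusted p = 7.6e-22, or 0.00036 with an estimated correlation). CYP26B1 was higher by 1.96 (95% interval 1.55 to 2.38, adjusted p = 0.00025), STRA6 by 1.58 (1.13 to 2.03, 0.0055), DHRS3 by 1.21 (1.02 to 1.39, 6.5e-06) and TGM2 by 0.78 (0.60 to 0.95, 0.00045), while NRIP1 and HOXA5 were higher by 0.51 and 0.99. PTGES was higher by 1.62 (adjusted p = 0.00025), and ADAMTS1 (-0.58, 0.041) and HMGA2 (-0.45, 0.033) were lower. The LXR targets ABCA1 (0.25, interval -0.01 to 0.50, adjusted p = 0.81), SCD (0.49, 0.15 to 0.82, 0.53) and SREBF1 (0.25, -0.20 to 0.69, 0.95) did not pass. The fatty acid synthesis list was higher with A41 (camera adjusted p = 0.00014, or 0.0075 with an estimated correlation), with 0 members past the threshold over all genes in limma and 3 when adjusted over the list alone. Calls outside the naming rule, chosen after their values were seen, included the transcription factor genes SMAD3 (0.70, adjusted p = 0.0086) and GATA6 (0.59) and ID1 (0.51, 0.0027). STX16-NPEPL1 (7.50, adjusted p = 0.035) and ADAMTS1 were lost when any 1 of the 6 libraries was left out and HMGA2 in 5 omissions. The count was 8 without bexarotene 2, 8 without bexarotene 3, and 12, 10 and 8 without A41 1, 2 and 3. It was also 8 without the 3 libraries rich in ribosomal RNA, where DHRS3 (0.00060), CYP26B1 (0.0044), STRA6 (0.0044), PTGES (0.0019) and TGM2 (0.0029) passed. There ID1 (adjusted p = 0.0046) passed as well, while SMAD3 (0.13), NRIP1 (0.18) and HOXA5 (0.19) did not.

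**Figure D4:**
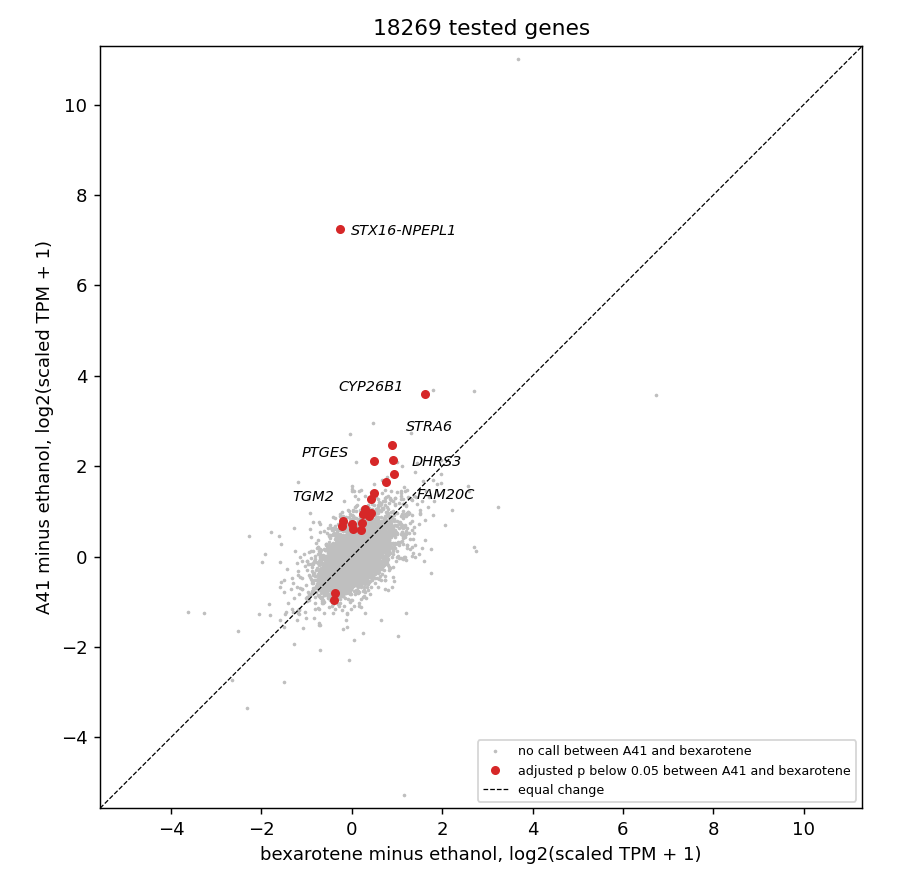
Log2 fold change against ethanol of 18269 genes with bexarotene (x axis) and A41 (y axis), with the dashed line marking equality and the 21 genes that differed between the compounds in red. CYP26B1 lies at 1.62 and 3.59, and DHRS3 at 0.92 and 2.13.

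A34 differed from A41 in 13 genes, all higher in A41, A41 from A80 in 23 (20 higher, 3 lower) and A41 from A98 in 24 (19 higher, 5 lower). DHRS3 differed by -0.99 for A34 against A41 (adjusted p = 0.0001), and was higher in A41 by 1.16 than in A80 (1.2e-05) and by 1.18 than in A98 (8.9e-06). CYP26B1 differed by -1.65 (0.0019), 2.06 (0.0002) and 1.93 (0.00033), and STRA6 by -1.56 (0.0076), 1.78 (0.0014) and 1.68 (0.0026) in the same order. ABCA1 differed between A34 and A41 by 0.15 (95% interval -0.11 to 0.40) and SCD by 0.03 (-0.30 to 0.37). The RAR list passed in the 3 comparisons (camera adjusted p = 6.7e-15, 3.2e-16 and 9.6e-18, or 0.0022, 0.0014 and 0.00098 with an estimated correlation). An F test for any difference among the 5 rexinoids passed in 12 genes, among them CYP26B1, DHRS3, STRA6, PTGES, TGM2 and NRIP1. The A34 count was 8 without A34 1, 6 without A41 2 and 5 without A41 3. The A80 count was 15 without A41 2, 11 without A41 3, 14 without A80 1 and 9 without A80 2, and the A98 count was 13, 11 and 14 without A41 1, 2 and 3 and 8 without A98 2 or A98 3. Without the 3 libraries rich in ribosomal RNA the counts were 6, 7 and 6, and the F test count was 7, 7 and 5 without A41 1, 2 and 3, 7 without A98 2 and 21 without A34 3.

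No protein-coding gene passed the test between bexarotene and A34, A80 or A98, and the intervals of single genes bound the differences that these libraries leave open. By limma 0 genes differed for A34 (950 with an unadjusted p under 0.05) and 0 for A80 (1108), and 1 for A98, the small nucleolar RNA gene SNORA70G (1.34, adjusted p = 0.019), named after its value was seen. DHRS3 differed from bexarotene by 0.22 (95% interval 0.03 to 0.40) with A34, 0.05 (-0.13 to 0.24) with A80 and 0.03 (-0.16 to 0.21) with A98, and CYP26B1 by 0.32 (-0.10 to 0.74), -0.10 (-0.52 to 0.32) and 0.04 (-0.38 to 0.46). ABCA1 differed by 0.39 (0.14 to 0.65) with A34, -0.26 (-0.51 to -0.0003, adjusted p = 0.80) with A80 and 0.19 (-0.07 to 0.44) with A98, and SCD by 0.52 (0.19 to 0.86), -0.18 (-0.52 to 0.15) and 0.19 (-0.14 to 0.53) with A34, A80 and A98. Between the coded compounds, A34 exceeded A80 by 0.65 in ABCA1 (0.39 to 0.91, adjusted p = 0.62) and 0.70 in SCD (0.37 to 1.04), and A80 lay from A98 by -0.44 in ABCA1 (-0.70 to -0.19, adjusted p = 1), differences that did not pass over all genes. For A34 against A80, 0 genes passed (648 with an unadjusted p under 0.05), and SNORA70G alone passed for A34 against A98 and for A80 against A98, at -1.34 in both. Its change had the same size against bexarotene, A34 and A80, as a gene without signal in those groups would give. These calls rest on the same A98 libraries and are not independent of each other. The hypoxia list was higher than bexarotene with A34 (camera adjusted p = 1.2e-05) and A80 (8.4e-06), with adjusted p = 0.69 and 0.78 with an estimated correlation. SNORA70G was lost against bexarotene without bexarotene 1 or 2 or A98 2, against A34 without A34 1, 2 or 3 or A98 2 or 3, and against A80 without any 1 of the 6 libraries, each leaving a count of 0. The count against bexarotene was 4 without A98 1, and that against A34 was 2 without A98 1. Without the 3 libraries rich in ribosomal RNA, these 3 counts were 0, while A34 and A80 each differed from bexarotene in 1 gene. Leaving out bexarotene 1, bexarotene 3 or A34 2 also gave 1 gene for A34 against bexarotene, as did bexarotene 1 or 3 for A80, and A34 2 or 3 for A34 against A80.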

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

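The tests of the RAR, hypoxia and STX16-NPEPL1 patterns were chosen only after the results were seen, while the counts over other splits of the libraries were planned.

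The difference between compounds was itself tested and passed for 21 genes between A41 and bexarotene, 13 between A34 and A41, 23 between A41 and A80, 24 between A41 and A98, and 12 in the F test among the 5 rexinoids. Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For those splits the real and highest other counts were 21 and 0 for A41 against bexarotene, 13 and 4 for A34 against A41, 23 and 1 for A41 against A80, and 24 and 2 for A41 against A98, with 1 split of the 10 as large in each. Against ethanol they were 10 and 1 for bexarotene, 15 and 5 for A34, 138 and 1 for A41, 8 and 1 for A80, and 6 and 1 for A98, with 1 split as large in each. All 10 splits gave at least the real count of 0 for A34 against bexarotene, A80 against bexarotene (highest other 1) and A34 against A80 (highest other 3). For SNORA70G, the 1 gene of its comparisons, the highest other count was 0 against bexarotene and against A80 and 1 against A34, with 1, 1 and 4 splits as large. For the F test, 1 of 100 drawn splits, the real one, reached 12 genes and the highest other gave 5. For the mean of the 5 rexinoids, 2 of 100 drawn splits reached 37 genes, the real one among them. The other, with A34 1, A34 2 and A80 1 in ethanol's place, gave 187 genes, which points to a structure of the samples. The draws mix libraries of different treatments within a group, which widens the spread in their fits and can lower their counts. Counts as large were rare among these draws, but for this reason they do not exclude chance.

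RAR target genes were higher in A41 than in bexarotene by 0.747 on the log2 scale as a list mean. Ribosomal RNA in bexarotene 1 and A41 2 is argued against as the cause, since the difference was 0.858 without these libraries. An extra response of equal size in RAR and LXR targets is argued against too. The RAR list minus the LXR list lay at 0.409 to 0.803 in A41 and -0.155 to 0.228 in the 12 other rexinoid libraries. The difference was 0.592 (exact permutation p = 0.00220, two-sided, the smallest that 455 splits can give, or 0.00330 adjusted over the 3 relations tested). A41 was singled out after its RAR list was seen, and this p does not allow for that choice among the rexinoids. A larger response that is unequal between the lists was not tested. The RAR list alone differed by 0.696 (exact permutation p = 0.00220) and the LXR list by 0.104 (exact permutation p = 0.180). As a hypothesis, A41 may act more on RAR targets than the other rexinoids at this dose, and a direct action on RAR or another potency was not tested.

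Hypoxia and glycolysis genes spread widely between libraries and lay higher in the rexinoid groups, by 0.602 over ethanol. Ribosomal RNA in 3 libraries is argued against, since the difference was 0.657 without them. For the spread, a culture state shared by libraries of the same replicate number may contribute, because exchanging numbers within groups rarely gave as large a spread between numbers (exact permutation p = 0.000257 over 46656 arrangements, adjusted over 5 lists 0.000643; unfolded protein, NF-kB and RAR lists 0.000643, 0.00129 and 0.0104, LXR 0.109). Such a state is argued against as the cause of the difference from ethanol, since each number of the titles includes an ethanol library: exchanging ethanol with rexinoid libraries of the same number gave exact permutation p = 0.00926 over 216 arrangements (0.0167 for the file numbers, the smallest that 60 can give). The treatment stays open for that difference (exact permutation p = 0.0257 when numbers are ignored, two-sided), as does a state of the ethanol cultures alone, which no label would show.

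STX16-NPEPL1 stood at 167 to 442 scaled TPM in the 3 A41 libraries and at 334 in A34 3, against 0.240 to 1.82 in the other 14. A41 RNA in A34 3 is argued against, since CYP26B1 was 13.1 there, under the lowest A41 value of 52.3 and under the other A34 libraries. RAB11FIP4 had a like pattern, 1.34 to 2.36 in A41 and 1.64 in A34 3 against at most 0.179 elsewhere. STX16 stood at 44.7 to 50.7 in A41 and 42.4 in A34 3, against 41.7 to 52.4 in the other 14. It did not fall, which argues against a shift of reads from STX16. NPEPL1 stood at 2.03 to 5.92 in A41 and 5.39 in A34 3, against 4.74 to 8.04, so it was partly lower in A41. No biological explanation was tested for A34 3, and the source of the signal, including a shift of reads from other overlapping genes, stays open.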

How the results depend on the processing

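Leaving out the 3 libraries rich in ribosomal RNA and using the ribosomal RNA share as a covariate were chosen after seeing the data, and the other alternatives were planned. Of 393 values of named genes, 73 passed the test, and 0 of these 73 reversed under any alternative run. Among the values that did not pass, 37 changed sign with TPM as deposited, 38 with rescaled TPM, 17 without the 3 libraries and 14 with library weights. Of the 73, 73 were kept with FPKM and with library weights, 72 with a pseudocount of 0.1, 71 with 5, 72 with robust moderation, 58 without a trend, 67 with quantile normalization, 59 without a filter, 70 with the covariate, 71 with the replicate block, 60 with the block from file numbers, 35 without the 3 libraries, 23 in fits of 6 libraries, 7 with rescaled TPM and 5 with TPM as deposited. FPKM is proportional to TPM within a library, so after the scaling only the relative size of the pseudocount differs. The values kept with FPKM are therefore no independent check. Of 320 values that did not pass, 31 passed with library weights, 31 with the replicate block and 20 with the block from file numbers. With either block these included NDRG1, VEGFA, DDIT4 and ANGPTL4 for A34 and for A80 against ethanol, so those genes are not settled as unchanged. TPM as deposited moved the median log2 fold change of all genes against ethanol by -0.27 to 0.15 and rescaled TPM (without mitochondrial and short genes) by -0.28 to 0.16. Ribosomal RNA lowers the share of other genes in 3 libraries, but a comparison without those libraries also moved, A80 against A98 by -0.07 with TPM as deposited. Quantile normalization moved it by -0.02 to 0.01. Over the 26 lists in 16 comparisons, median, mean and test differed in sign in 1 called pair (small RNAs in the mean of rexinoids, median 0.33, mean -0.22, camera adjusted p = 0.017) and in 50 of the pairs not called. The cause of a moved value was not tested unless named. Depth limits genes near 1 TPM, and with 2 libraries left in a group the call rests on the spread of all groups.

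Counts of changed genes moved as follows. Leaving out 1 library gave 5 to 9 for bexarotene against ethanol (10 with all), 8 to 18 for A34 (15), 71 to 113 for A41 (138), 2 to 7 for A80 (8) and 5 to 8 for A98 (6). It gave 0 to 1 for A34 against bexarotene (0), 8 to 16 for A41 against bexarotene (21), 0 to 1 for A80 against bexarotene (0), 0 to 4 for A98 against bexarotene (1), 5 to 13 for A34 against A41 (13), 0 to 1 for A34 against A80 (0), 0 to 2 for A34 against A98 (1), 9 to 28 for A41 against A80 (23), 8 to 16 for A41 against A98 (24), 0 for A80 against A98 (1), 15 to 41 for the mean of rexinoids (37) and 5 to 21 for the F test (12).

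TPM as deposited gave 0 genes for bexarotene, 0 for A34, 4 for A41, 0 for A80 and 2 for A98 against ethanol, 1 for A41 against bexarotene, 0 for A34 against A41, 0 for A34 against A98, 1 for A41 against A80, 1 for A41 against A98, 0 for A80 against A98, 1 for the mean and 2 for the F test. Rescaled TPM gave 0, 3, 9, 3 and 1 for bexarotene, A34, A41, A80 and A98 against ethanol, 3 for A34, 3 for A41 and 0 for A98 against bexarotene, 7 for A34 against A41, 1 for A34 against A80, 4 for A34 against A98, 1 for A41 against A80, 3 for A41 against A98, 0 for A80 against A98 and 7 for the mean. Quantile normalization gave 14 for A41 against A80 and 15 for A41 against A98. Higher and lower calls with TPM as deposited were 4 and 0 for A41 (93 and 45 by median of ratios), 1 and 1 for A98 (6 and 0), 0 and 1 for A98 against bexarotene (1 and 0), 1 and 0 for A41 against A80 (20 and 3), 1 and 0 for A41 against A98 (19 and 5), and 1 and 0 for the mean (33 and 4). With rescaled TPM they were 7 and 2 for A41, 3 and 0 for A34 (13 and 2), 0 and 1 for A98, 2 and 1 for A41 against bexarotene (19 and 2), 4 and 3 for A34 against A41 (0 and 13), 1 and 0 for A41 against A80 and 2 and 1 for A41 against A98.

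No filter gave 20 for bexarotene and 14 for A80 against ethanol, 5 for A34, 3 for A80 and 6 for A98 against bexarotene, 2 for A34 against A80, 2 for A34 against A98, 2 for A80 against A98 and 20 for the F test. A pseudocount of 0.1 or a mean TPM of at least 5 gave 0 for A98 against bexarotene, A34 against A98 and A80 against A98, and a pseudocount of 5 gave 32 for A41 against bexarotene. Library weights, from 0.359 for A41 2 to 3.28 for A80 2, gave 89 for A34, 547 for A41, 261 for A80 and 24 for A98 against ethanol, 94 for A41 against bexarotene, 73 for A34 against A41, 1 for A34 against A80, 475 for A41 against A80, 147 for A41 against A98, 277 for the mean and 102 for the F test. Without the 3 libraries the counts were 2 for bexarotene, 48 for A41 and 2 for A80 against ethanol, 1 for A34, 8 for A41, 1 for A80 and 0 for A98 against bexarotene, 6 for A34 against A41, 0 for A34 against A98, 7 for A41 against A80, 6 for A41 against A98, 0 for A80 against A98 and 16 for the mean. The covariate gave 26 for A34 and 16 for A80 against ethanol, 0 for A98 against bexarotene, 7 for A34 against A41, 15 for A41 against A80 and 103 for the mean. Fits of 6 libraries, which have fewer residual degrees of freedom, gave 4 for bexarotene, 1 for A34, 33 for A41 and 0 for A80 against ethanol, 3 for A41 and 1 for A80 against bexarotene, 0 for A34 against A41, 3 for A34 against A98, 4 for A41 against A80 and 11 for A41 against A98. Requiring a 2-fold change left 5 for bexarotene, 6 for A34, 32 for A41, 3 for A80 and 4 for A98 against ethanol, 5 for A41 against bexarotene, 4 for A34 against A41, 7 for A41 against A80, 8 for A41 against A98 and 8 for the mean. Of 121 list calls with the preset correlation, 18 remained with an estimated correlation, 48 passed with fry, and 8 passed with an estimated correlation without the 3 libraries.

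The replicate numbers did not meet the requirement for a pairing, a correlation over 0.1 in every pair, although 4 of the 5 lists tested spread by number. Those 5 were picked from the 26 lists after the values were seen. Their spread was tested with the numbers of the titles only. Over 45 pairs of libraries sharing a number in the titles, deviations from the group means correlated at 0.030 on average (-0.356 to 0.306, 11 of 45 over 0.1), against -0.0141 over the other 90 pairs, and 9 of 18 libraries correlated best with their own number (7 of 18 for the file numbers). With the replicate block the counts were 166 for A34, 117 for A80, 0 for A98 against bexarotene, 29 for A34 against A41, 0 for A34 against A98, 75 for A41 against A80, 0 for A80 against A98, 147 for the mean and 29 for the F test. The block from file numbers gave 57 for A34, 51 for A80, 15 for A98, 0 for A98 against bexarotene, 0 for A34 against A98, 63 for A41 against A80, 0 for A80 against A98 and 99 for the mean, and 197 for A41 came from the replicate block of the titles (138 without it).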

Other observations

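The tests of the RAR and LXR list levels quoted here were chosen only after the result was seen; the gene values come from the planned comparisons, and the genes named were picked after their values were seen.

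Outside the naming rule, the calls for A41 against ethanol included these single genes, with no test of a shared theme. The signal transducer SMAD3 rose by 0.94 (adjusted p = 0.0001), LTBP3, which binds latent TGF-beta, by 1.28 (0.0001), and ID1 by 0.89 (1.7e-06). HOTAIRM1, a noncoding RNA at the HOXA locus that overlaps its neighbours, rose by 0.73 (adjusted p = 0.0036), beside HOXA5 at 0.79 (0.025). Without the 3 libraries rich in ribosomal RNA, HOTAIRM1 (adjusted p = 0.077) and HOXA5 (0.14) did not pass. SMAD3 (0.0040), ID1 (4.4e-05) and PTPRJ (0.013) passed there. The tyrosine phosphatase PTPRJ rose by 0.79 (adjusted p = 0.00073), the semaphorin and VEGF co-receptor NRP2 by 1.14 (0.0014), the metalloprotease inhibitor TIMP1 by 0.92 (0.027) and the lipid peroxide reductase GPX4 by 0.68 (0.0025). SPRY4 fell by 0.42, the phosphatase DUSP4 by 0.46 and the receptor AXL by 0.35.

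Libraries of the other rexinoids lay from 0.196 to 0.610 in the LXR list and those of A41 from 0.477 to 0.604, so the ranges overlapped there, while in the RAR list A41 (1.01 to 1.28) lay above the other 12 (0.277 to 0.627). The LXR targets ABCG1 and MYLIP stayed below the level for testing, with highest TPM of 0.556 and 0.760 in any library, as did the vitamin D target CYP24A1 at 0.935 and APOE at 1.31.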
